A study of Mus musculus with 2 samples.

How the data were processed

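Nuclei were isolated from whole salivary glands of mice aged 20 days without selection of a cell type, and 3' single-nucleus libraries were made with the 10x Chromium chemistry, per the labels' protocols. There were 2 libraries, 1 from a Csf2 heterozygous gland (control) and 1 from a Csf2 null gland (null), so each genotype had 1 library. The deposited values were raw UMI counts per gene and barcode, written by Cell Ranger 7.0.0 per the file headers, on genome build GRCm39 per the submitters' processing notes. Neither the gene annotation nor whether intronic reads were counted was stated. The files paired 26033 gene identifiers with symbols, which were used as given. The barcodes had been chosen upstream: 0 barcodes in either library had under 100 UMIs, and the lowest UMI number was 531 in the control and 430 in the null library.

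Barcodes were kept with at least 500 UMIs, at least 300 genes and under 5% mitochondrial UMIs, and Scrublet doublets were removed per library with Scanpy 1.11.5. Scrublet marked 9 of 67940 control and 35 of 55517 null barcodes, under 0.1% of each, and was taken as not having worked on these files. Run again on the nuclei alone, it marked 238 of 9017 (2.64%) and 532 of 13764 (3.87%). The libraries were clustered together without batch correction on 2000 variable genes ranked within each library, 30 principal components, 20 exact neighbours and Leiden resolution 1.0 (igraph 0.11.9, scikit-learn 1.9.0). Mitochondrial, ribosomal protein and sex-linked genes and Csf2 were left out of the variable genes. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 did the rest.

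Of 19 clusters, 8 had a share of UMIs from the 8 most abundant secretory genes of at least 0.75 times that of the barcodes under 1000 UMIs and were called free-RNA clusters, that is, droplets that held RNA released from broken cells. The other 11 clusters were taken as nuclei. A cluster was named from marker lists fixed in advance when at least 3 markers were at least 2-fold above the other nuclei with at least 10 UMIs. Cluster 4, which had acinar markers, had 0 of them and 1 marker of another class among its top 10 genes and is given by number, as is cluster 11, which had too few markers. The free-RNA rule and the naming rule were set on the clustering at resolution 1.0 after it had been seen, and were then applied without change to the 8 alternative clusterings. The macrophage-like cluster was clustered again (1000 variable genes, 15 components, 15 neighbours) after the data had been examined.

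Shares were given with exact binomial 95% intervals and sums with exact Poisson 95% intervals. UMIs were summed per class and library, scaled to CPM of that class total, and compared as the log2 ratio of null over control with an exact conditional binomial 95% interval. All these intervals cover counting error only. With 1 library per genotype no test between genotypes was possible, the differences have no replicate check, and no p-value is given. Ratios against 0 UMIs were bounded with a floor of 3 counts. A class was compared where it held at least 50 nuclei in each library.

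Genes were named by a rule of size fixed before the data were examined, on the bound of the counting interval nearest to no difference. The 12 highest and 12 lowest were taken in macrophage-like nuclei (at least 20 UMIs over both libraries), 5 and 5 in each other class (at least 50) and 10 and 10 in the whole tissue (at least 200). Mitochondrial, ribosomal protein, sex-linked and unnamed predicted genes were left out, as were, outside the acinar classes, the 100 most abundant genes of the acinar nuclei. Csf2, its receptor genes, Itgax, Cx3cr1, Adgre1 and Csf1r were always given in macrophage-like nuclei. The 20 gene lists were also fixed then. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression, which describes these libraries alone. Outside macrophage-like nuclei and the whole tissue, lists were followed in classes picked after their values had been seen.

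Simulated data tested the steps. With 8373 genes at the depth of the macrophage-like nuclei, the interval lay on the right side of 0 for 74.7% of genes changed 2-fold and 98.9% of those changed 4-fold. All 24 of 24 named genes had been changed in the simulation. With 9635 genes at the depth of the luminal duct-like nuclei, the shares were 95.8% and 100%. Both simulated libraries were drawn from a pooled profile with counting error alone. They had no difference in free RNA, no mixed subclusters and no variation between preparations, so they cannot show how the naming rule works where these occur.

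The plan set the shares over all nuclei kept, counted as the barcodes that passed the filters. That count of kept barcodes is called the planned denominator here, and it stayed the main one. Since 86.7% of the kept control and 75.2% of the kept null barcodes were then called free RNA, it is mostly not a count of nuclei. After both values had been seen, 2 further denominators were added: barcodes outside the free-RNA clusters, and all barcodes of the file. The former served briefly as the main denominator before the planned one was restored, and the 3 are printed side by side. The planned subtraction of free RNA needed barcodes under 100 UMIs, so the profile of the free-RNA clusters was used, scaled by acinar genes in the macrophage-like nuclei (40.1% of control and 43.2% of null UMIs). Other alternatives changed the UMI, mitochondrial and doublet filters, the resolution, the number of variable genes, joint clustering, the marker rule, depth, scaling and the minimum count.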

Results

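The 2 libraries held 68460 barcodes with 76002888 UMIs (control, Csf2 heterozygous) and 74339 barcodes with 75630815 UMIs (null). After filters 67931 and 55482 barcodes remained. Most of them carried the profile of free RNA: 58914 (86.7%) in the control and 41718 (75.2%) in the null library, with median UMI numbers of 791 and 797. The clusters taken as nuclei held 9017 and 13764 barcodes, with median UMI numbers of 2747 and 1982. The control thus had 6.53 free-RNA barcodes per nucleus and the null library 3.03. There was 1 library per genotype, so each difference below is a difference between 2 libraries.

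Csf2, which encodes the cytokine GM-CSF, gave 5 UMIs in the control library (95% Poisson interval 1.62 to 11.7) and 0 in the null library (0 to 3.69). Of the 5 UMIs, 2 lay in intercalated duct-like nuclei and 3 in free-RNA barcodes. Macrophage-like nuclei had 0 in both libraries. The counts went with the labels but were too few to check them firmly, and where the deletion lies relative to the 3' tag was not stated.

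The series title concerns gland macrophages that GM-CSF maintains, so the share of macrophage-like nuclei was the first comparison. These nuclei, with 15 of 16 macrophage markers including Csf1r, Adgre1, Mrc1 and C1qa, numbered 313 in the control and 345 in the null library. The direction of the difference depended on the denominator. Of all kept barcodes, the planned denominator, they were 0.461% (95% interval 0.411 to 0.515) in the control and 0.622% (0.558 to 0.691) in the null library, a log2 ratio of 0.43 (0.21 to 0.66). Of the barcodes outside the free-RNA clusters, a denominator added after the data were seen, they were 3.47% (3.10 to 3.87) and 2.51% (2.25 to 2.78), a log2 ratio of -0.47 (-0.69 to -0.24). Of all barcodes of the file, also added, the log2 ratio was 0.02 (-0.20 to 0.25). Most kept barcodes were free RNA, and each class taken as nuclei made up a larger share of the kept barcodes in the null library. The shares of kept and of all barcodes thus depend on the number of free-RNA barcodes per nucleus. The share among nuclei was lower, but rests on a division into nuclei and free RNA set after the data were seen. No direction for macrophage abundance is therefore concluded.

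Mucous acinar-like nuclei, which had the mucin gene Muc19 and the transcription factor gene Spdef, had a larger share in the null library under each of the 3 denominators when named by cluster. They numbered 339 in the control and 942 in the null library, 3.76% (3.38 to 4.17) and 6.84% (6.43 to 7.28) of the nuclei, a log2 ratio of 0.86 (0.68 to 1.05), and 1.77 (1.59 to 1.95) of all kept barcodes. The rule of at least 3 markers, which took 27.0% of control and 22.3% of null nuclei, turned the direction among nuclei (-0.28, -0.36 to -0.20) and gave 0.32 of all kept barcodes. With each nucleus thinned to 500 UMIs, which matches depth, the same rule took 133 control and 266 null nuclei, a log2 ratio of 0.39 (0.08 to 0.70). Among nuclei, ionocyte-like nuclei had a log2 ratio of -0.54 (-0.84 to -0.23), Schwann-like nuclei -0.53 (-0.96 to -0.10) and luminal duct-like nuclei -0.27 (-0.40 to -0.15). The Schwann-like interval included 0 with at least 1000 UMIs (-0.42), with under 1% mitochondrial UMIs (-0.38) and outside the acinar clusters (-0.38). The luminal duct-like difference was also smaller outside the acinar clusters, with an interval that ended near 0. Fibroblast-like, endothelial-like and myoepithelial-like nuclei and clusters 4 and 11 lay between -0.14 and 0.05, with intervals that included 0, and intercalated duct-like nuclei were at 0.09 (-0.08 to 0.26). Outside the acinar clusters the intercalated duct-like interval lay above 0. For cluster 4 the interval lay above 0 with at least 1000 UMIs (0.12, 0.07 to 0.18), with more variable genes (0.12), with under 1% mitochondrial UMIs (0.07) and at resolutions 0.5 and 2.0 (both 0.06). Under the same marker rule, fibroblast-like nuclei were at -0.34 (-0.43 to -0.24) and intercalated duct-like nuclei at -0.56 (-0.86 to -0.27), and with more variable genes in the clustering fibroblast-like nuclei were at -0.15 (-0.25 to -0.04). The endothelial-like value rested on a mixed cluster of 310 control and 456 null nuclei. At resolution 2.0 it held 99 and 111, with a log2 ratio of -0.46 (-0.86 to -0.05), and with at least 1000 UMIs 115 and 126, with -0.55 (-0.92 to -0.17). Of all kept barcodes, the planned denominator, each of these classes had a ratio above 0. Ionocyte-like nuclei were 0.258% in the control and 0.332% in the null library, Schwann-like 0.134% and 0.173%, and luminal duct-like 1.42% and 2.20%. Fibroblast-like nuclei were 1.39% and 2.46%, and cluster 4 took 6.53% and 12.6%.

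**Figure D1:**
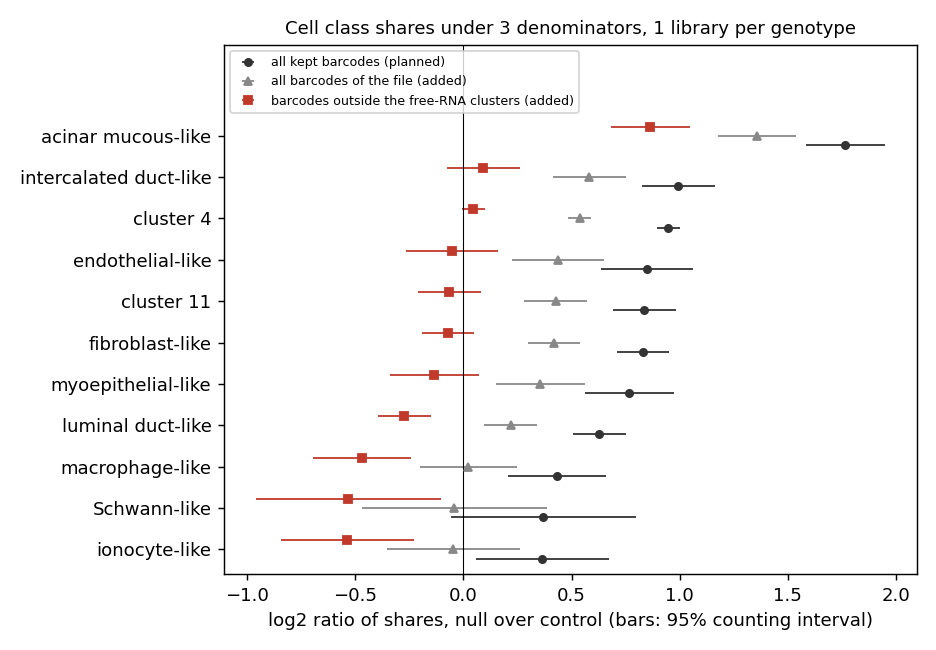
Log2 ratio of the share of each class, null over control, with 95% counting intervals, under 3 denominators (1 library per genotype). Macrophage-like nuclei lie at 0.43 of all kept barcodes and at -0.47 of the barcodes outside the free-RNA clusters, and mucous acinar-like clusters lie above 0 under each.

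Within the macrophage-like cluster, a subcluster led by Cd163, F13a1 and Colec12, genes of resident macrophages, held 101 control and 73 null nuclei. That was 32.3% (27.1 to 37.8) and 21.2% (17.0 to 25.9) of the cluster, a log2 ratio of -0.61 (-1.06 to -0.16). The ratio was -0.18 (-0.63 to 0.27) of all kept barcodes and -1.08 (-1.53 to -0.63) among nuclei. At subcluster resolution 0.5 the subcluster with Cd163 was at -0.08 of the cluster. At 2.0 a subcluster led by Timd4 and Lyve1 held 47 and 21 nuclei (-1.30), but had 0 macrophage markers and 1 marker of another class among its top 10 genes, so it is not named. Another, led by Clec4a4, held 36 and 24 (-0.73). A subcluster led by Lhfpl2 and Tgfbr1 held 45 and 66 nuclei, with a log2 ratio of 0.41 (-0.16 to 0.99) of the cluster. It was at 0.84 (0.28 to 1.42) of all kept barcodes and at -0.06 (-0.63 to 0.52) among nuclei, so its direction depended on the denominator. One led by Kcnip4 and Gria3 held 46 control and 1 null Kcnip4 UMIs, of 83 and 24 in the class, so its leading gene differed between the libraries and its share is not given here. The cluster also held an endothelial-like subcluster with Flt1 and Emcn (15 and 33 nuclei, 0.997, 0.08 to 1.98) and 1 of low UMI number (40 and 69, 0.65, 0.06 to 1.25), with Mrc1, F13a1 and Csf1r near their level in the other subclusters. A further subcluster, of 21 and 16 nuclei, was led by Grip1 and Tafa1, which were also top 10 genes of the intercalated duct-like cluster. Its median UMI numbers, 4842 and 3136, were the highest of the subclusters. Gene values of the class include all of these, and also a subcluster of 24 and 20 nuclei with NK or ILC1 markers. No cluster met the rule for ILC2, the lymphoid cells that the title names as the source of GM-CSF. A subcluster with 6 ILC2 markers, among them Gata3 and Il1rl1, held 6 control and 7 null nuclei, and had more T cell than ILC2 markers among its top 10 genes.

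In macrophage-like nuclei (781463 control and 664286 null UMIs), the GM-CSF receptor gene Csf2ra had 135 control and 98 null UMIs, a log2 ratio of -0.23 (-0.62 to 0.16). Csf2rb, the signalling subunit gene, had 29 and 26 UMIs (0.08, -0.74 to 0.89), of which 10 and 0 lay in the subcluster led by Aldh1a2 and Clec9a, while its paralog Csf2rb2 had 21 and 5 (-1.84, -3.60 to -0.39). Reads shared between these paralogs make the split uncertain. Itgax was at 0.17 (-0.72 to 1.06), Cx3cr1 at 0.42 (-0.08 to 0.91), Adgre1 at -0.24 (-0.71 to 0.23) and Csf1r at -0.05 (-0.31 to 0.22). Apart from Csf2rb2, whose split from Csf2rb is uncertain, no class value of these genes thus differed beyond counting error. The class values mix subclusters, for which no intervals were computed. In the subcluster led by Lhfpl2 and Tgfbr1, Adgre1 had 27 and 13 UMIs (-1.34) and Cx3cr1 17 and 37 (0.83). In that led by Cd163, Adgre1 was at 0.04 and Cx3cr1 at -0.87. Csf2ra was at -0.65 and -0.70 in these subclusters. It was higher in those led by Grip1 (4 and 7 UMIs) and Kif23 (1 and 2) and in that of low UMI number (1 and 4). Of 9 measured GM-CSF-responsive myeloid genes, 6 were lower and 3 higher in the null library, with a median of -0.27 at percentile 10.2 of random lists. Of 11 receptor and JAK-STAT5 pathway genes, 9 were lower and 2 higher (median -0.23, percentile 12.8), with the kinase gene Jak2 at -0.75 (-1.30 to -0.22) and the STAT5 target Cish at -0.97 (-2.03 to 0.01). In these nuclei neither list stood apart from random lists.

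The perivascular and LYVE1-type genes had a median of -0.30 (percentile 4.03), with 9 of 13 lower. Stab1 was at -0.55 (-0.74 to -0.35), the growth factor gene Gas6 at -0.78 (-1.24 to -0.33) and Mrc1 at -0.32 (-0.46 to -0.18), but F13a1 was at 0.18 (0.07 to 0.29). Mrc1, F13a1 and Stab1 also define the cluster. Within the subcluster led by Cd163, Mrc1 was at -0.01 (726 and 417 UMIs), F13a1 at 0.62 (1008 and 894) and Lyve1 at -0.59 (26 and 10). Mrc1 was at -0.55 in the subcluster led by Kcnip4 and at 0.62 in that led by Grip1. The class value of Mrc1 thus mixes the shares of subclusters with the levels within them. All 7 measured cell cycle genes were higher (median 0.55, percentile 99.4), led by Top2a at 0.99 (0.47 to 1.53), and the subcluster led by Lhfpl2 and Tgfbr1 held 2 control and 30 null of the 49 and 83 Top2a UMIs. The same list was at -0.29 (percentile 3.56) over all kept barcodes and at -0.84 in myoepithelial-like nuclei, where all 5 measured genes were lower, but at 0.50 in mucous acinar-like (percentile 99.7), 0.40 in luminal duct-like (98.8), 0.31 in intercalated duct-like and 0.18 in cluster 4 nuclei (95.5), where 6 of 13 genes were lower. The 3 measured ILC2 effector genes were lower, Gata3 with 17 and 4 UMIs, Il1rl1 with 44 and 17 and Il7r with 21 and 10 (median -1.14, percentile 0.635). The subcluster with ILC2 markers, of 6 and 7 nuclei, held 9 and 2 of the Gata3, 17 and 4 of the Il1rl1 and 8 and 3 of the Il7r UMIs, and the median was -0.40 with at least 1000 UMIs. All 6 collagen and extracellular matrix genes were lower (median -0.55, percentile 2.17). MHC class II genes (-0.18, percentile 25.0), lipid and lysosome genes (-0.20, 15.9), microglia-type genes (-0.05, 64.7), interferon-induced genes (-0.06, 48.8), NF-kB inflammatory genes (0.15, 67.1), immediate early and heat shock genes (-0.07, 54.8), endoplasmic reticulum stress genes (-0.11, 44.8), gland growth genes (0.02, 75.8), angiogenesis genes (-0.01, 57.5) and androgen-responsive duct products (0.12, 82.8) lay inside the random range. Of the niche growth factors 2 were measured (median -0.66, percentile 5.23). Acinar secretory products, which these cells do not make, were at 0.50 (percentile 100), and acinar markers took 2.46% of control and 4.06% of null UMIs of the class.

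Among the 24 genes named in macrophage-like nuclei, the nuclear receptor gene Nr4a3 had 58 control and 7 null UMIs, a log2 ratio of -2.82 (-4.19 to -1.68). Aldh1a2, an enzyme of retinoic acid synthesis, had 38 and 4 UMIs (-3.01, -4.96 to -1.54), but 37 and 2 of them lay in the subcluster led by Aldh1a2 and Clec9a, of 10 and 9 nuclei. The chemokine receptor gene Ccr1 had 24 and 3 (-2.77, -5.14 to -1.05) and Il17ra had 26 and 3 (-2.88, -5.25 to -1.17). Adamts9, Clnk, Ppargc1a, Kcnip4, Ccdc62, Camkk2, Jdp2 and a ribosomal RNA gene completed the lower side. Clnk was also the leading gene of the subcluster with NK or ILC1 markers, of 24 and 20 nuclei. Ppargc1a was at -1.36 (-1.80 to -0.93), and at 0.43 once the free RNA was subtracted. With that subtraction 5 of the 24 genes were still named, and Nr4a3 kept 27.9 control and 0 null UMIs. On the higher side, the stress-response gene Nupr1 had 81 and 204 UMIs (1.57, 1.19 to 1.96) and the peptide transporter gene Slc15a2 had 8 and 28 (2.04, 0.87 to 3.39). In the free RNA itself Nupr1 was at 1.27 and Slc15a2 at 1.74. The replication-linked chromatin assembly gene Chaf1a had 3 and 20 (2.97, 1.22 to 5.37). St18, Ndufa13, Lsm7, Zfp706, Atp6v1f, Drg1, G0s2, Wfdc18 and Ak6 were the others.

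**Figure D2:**
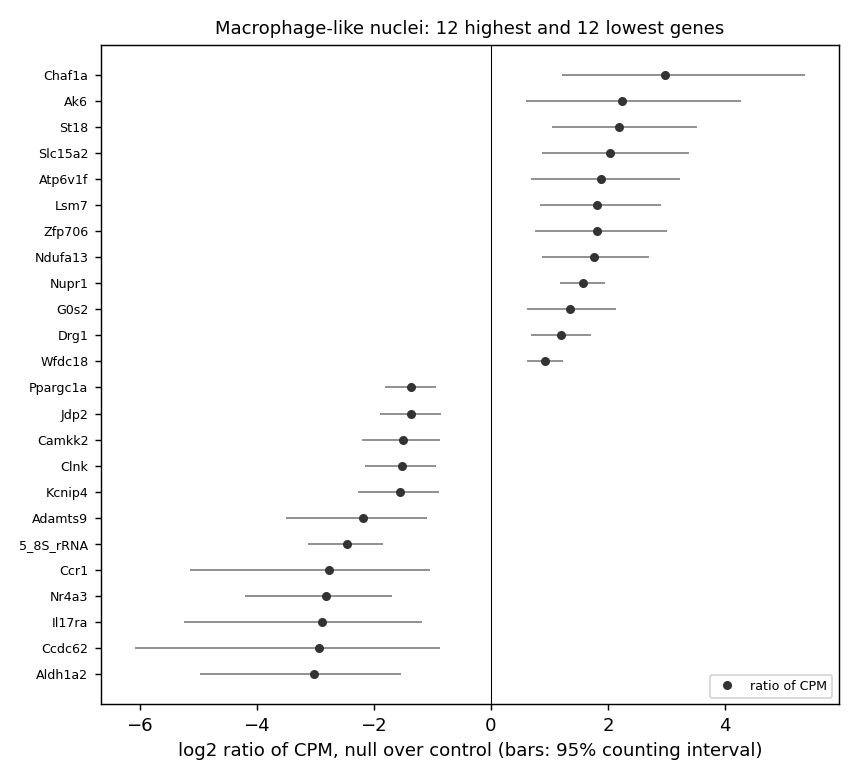
Log2 ratio of CPM, null over control, with 95% counting intervals, for the 12 highest and 12 lowest genes of macrophage-like nuclei (1 library per genotype). Nr4a3 (-2.82) and Clnk (-1.53) lie on the lower side, Chaf1a (2.97) and Nupr1 (1.57) on the higher. Clnk also leads the subcluster with NK or ILC1 markers.

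Some genes differed in the same direction across many classes. Nr4a3, the metabolic coactivator gene Ppargc1a, the insulin receptor substrate gene Irs2 and the repressor gene Bcl6 were lower in the null library in 40 of 40 gene and class pairs with at least 50 UMIs, with a median log2 ratio of -1.12. The pattern was noticed in the data. In the free RNA itself Nr4a3 was at -1.93, Ppargc1a at -1.71, Irs2 at -1.31 and Bcl6 at -1.22. A ribosomal RNA gene was also among the lowest genes of most classes, such as cluster 4 (-3.22) and fibroblast-like nuclei (-2.11). It was not named in endothelial-like or Schwann-like nuclei, and was at -2.34 in the free RNA. In fibroblast-like nuclei Nr4a3 had 1208 control and 168 null UMIs (-2.87, -3.11 to -2.63). In luminal duct-like nuclei Ppargc1a, one of the genes that define that cluster, had 16888 and 5034 (-1.57, -1.62 to -1.53). Slc15a2 was higher in cluster 4 (55 control and 559 null UMIs), fibroblast-like (4 and 65), endothelial-like (6 and 83) and cluster 11 nuclei (4 and 56).

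Fibroblast-like nuclei had lower extracellular matrix transcripts in the null library: 15 of 16 measured genes were lower (median -0.34, percentile 0.24), with Col1a1 at -0.91 (-1.12 to -0.69), Fbn1 at -0.65 (-0.77 to -0.54) and Col3a1 at -0.33 (-0.42 to -0.25). In the same nuclei acinar secretory products were higher (median 0.55, percentile 100), and acinar markers took 1.92% of control and 3.50% of null UMIs. The list was also lower in endothelial-like nuclei (13 of 15 genes, median -0.37, percentile 0), cluster 4 (14 of 16, -0.32, percentile 0.71) and luminal duct-like nuclei (12 of 15, -0.21). Gland growth genes were at -0.08 in fibroblast-like nuclei, inside the random range. In endothelial-like nuclei 7 of 8 angiogenesis genes were lower (median -0.34, percentile 0.42). That cluster was mixed, and none of its 10 named genes was named with at least 1000 UMIs (115 and 126 nuclei): the neuronal genes Alk, Ctnna2 and Elavl4 had 94, 87 and 75 control UMIs and 0 null UMIs. In luminal duct-like nuclei 10 of 14 androgen-responsive products were lower (median -0.23, percentile 6.29), with Egf at -0.52 (-0.71 to -0.34), and counts of the near-identical Klk1b genes are uncertain. In intercalated duct-like nuclei gland growth genes had a median of 0.16 (percentile 98.1), which was -0.27 with no minimum count.

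Over all kept barcodes, 3 paralogous secretory genes were among the 10 highest: Dcpp3 with 201662 control and 748586 null UMIs (log2 ratio 2.12), Dcpp1 (2.01) and Dcpp2 (1.97). Their reads may be divided between near-identical copies. Slc15a2 (1.97), Pglyrp1, which encodes an antibacterial protein (1.60), Xlr3a (34 and 189 UMIs, 2.70), Apobec2 (2.07), Ccdc24, Catsperb and Dpf1 were the other highest. Smr3a, a salivary peptide gene, had 766 control UMIs and 1 null UMI (-9.35, -14.66 to -6.87). Lower too were the hemoglobin genes Hbb-bs (1700 and 266 UMIs, -2.45), Hbb-bt, Hba-a1 and Hba-a2, with Mup4, Retnla, Kcne4, Elavl2 and a ribosomal RNA gene. Of these 20 genes, 9 were still named among barcodes outside the free-RNA clusters. The globins are transcripts of blood, and the 5 erythrocyte genes had a median of -2.45. The median log2 ratio of all measured genes was itself -0.10 over all kept barcodes and -0.19 in Schwann-like nuclei. Extracellular matrix genes were lower in 15 of 17 cases (median -0.37, percentile 0.03) and angiogenesis genes in 9 of 12 (median -0.43, percentile 0.43). GM-CSF-responsive myeloid genes were lower in 12 of 16 (median -0.31, percentile 3.53). These sums are not read from myeloid cells alone, since 8 genes of the list were also measured in fibroblast-like nuclei. In macrophage-like nuclei the list was at percentile 10.2. Acinar secretory products had a median of 0.17 (percentile 99.6) and a mean of -0.29. The epithelial cytokine gene Il33 was at -0.49 (-0.61 to -0.37), and its receptor gene Il1rl1 had 199 control and 85 null UMIs. The chemokine gene Ccl2 was at -1.71 (-2.41 to -1.07).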

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

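The free-RNA subtraction, the comparison of median UMIs of mucous nuclei and the share outside the acinar clusters are tests chosen after their results had been seen. In the null library 18807 barcodes had under 300 genes and were left out by that filter, against 507 in the control, 25.3% and 0.741% of the barcodes. They stand out as barcodes outside the kept data that differ in number between the libraries, and they enter only the values given over all barcodes of the file.

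The macrophage-like share of nuclei was lower in the null library, while the planned share of all kept barcodes was higher. With nuclei thinned to 500 UMIs and at least 3 macrophage markers required, the log2 ratio among nuclei was -0.77 (-1.16 to -0.37). That argues against lower depth as the reason among the barcodes taken as nuclei. It cannot cover null nuclei of low depth lost to the gene filter or to the free-RNA clusters. Outside the acinar clusters the log2 ratio of the share named by cluster was -0.32 (-0.54 to -0.09), which argues against more recovered acinar nuclei as the whole reason. Loss of Csf2, the recovery of nuclei in each preparation and the division into nuclei and free RNA stay open with 1 library per genotype, so a lower macrophage share in the null gland is a hypothesis.

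Mucous acinar-like nuclei, named by cluster, took a larger share in the null library, but not among nuclei named by at least 3 markers (-0.28). With nuclei thinned to 500 UMIs the same marker rule gave 0.39 (0.08 to 0.70). The null mucous nuclei were not deeper than the control ones (log2 ratio of the medians -0.59). Nuclei of all classes together also had fewer UMIs in the null library (medians of 1982 against 2747). The comparison therefore says nothing particular to mucous nuclei, and no conclusion on the filters is drawn from it. Mucous genes in the free RNA, which more mucous tissue would raise, had a median log2 ratio of -0.21, but the 4 measured genes spread from -0.64 to 0.20, so more mucous gland tissue in the preparation cannot be told apart from a difference in the nuclei. The genotype stays open and untested.

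Nr4a3, Ppargc1a, Irs2 and Bcl6 were lower in the null library across classes. After free RNA was subtracted, the median over 38 pairs was -0.81 (-1.05 to -0.38) and 31 were lower, an interval too wide to exclude free RNA as a contributor, although Ppargc1a in luminal duct-like nuclei kept 16171 of 16888 control UMIs. The shares of the macrophage-like nuclei were subtracted in each class, more than the acinar genes give in some, such as 28.6% of control UMIs in mucous acinar-like nuclei. Ppargc1a was left with 0 control UMIs there and in cluster 11, and those 2 pairs entered at 2.45 and 4.71. The difference between the groups of clock genes was 0.14 (-0.19 to 0.85), with Arntl alone at -0.83, and glucocorticoid and handling genes had a median of -0.15 (-0.44 to 0.07). Neither spread excludes another clock phase or another handling response at collection. These cannot be told apart from an effect of the genotype, which is confounded with the single preparation of each library.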

How the results depend on the processing

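No paired analysis was possible because each genotype had 1 library. The denominators, the subtraction of free RNA, the subclusters and Scrublet on the nuclei were chosen after seeing the data. The macrophage-like log2 ratio of 0.43 stayed above 0 under each alternative fixed before the data were examined, but not always within its counting interval. It fell below that interval with markers alone (0.12) and with thinned nuclei (0.11), and rose above it with each library clustered alone (0.72). Under the others it was 0.35 to 0.55. It was 0.022 of all barcodes of the file and -0.47 of barcodes outside the free-RNA clusters. With that last denominator the ratio also turned for cluster 11 (-0.066), endothelial-like (-0.053), fibroblast-like (-0.073) and myoepithelial-like nuclei (-0.14). It turned too for ionocyte-like (-0.54), luminal duct-like (-0.27) and Schwann-like nuclei (-0.53). Nuclei were 13.3% of kept control and 24.8% of kept null barcodes, which shifts every ratio between these denominators. The gene filter, which left out 507 control and 18807 null barcodes, is part of that difference. Of all barcodes of the file, ionocyte-like nuclei were at -0.047 and Schwann-like at -0.042. With markers alone, fibroblast-like nuclei were at -0.14, ionocyte-like at -0.17 and luminal duct-like at -0.17. With thinned nuclei, fibroblast-like were at -0.0084, luminal duct-like at -0.54, Schwann-like at -0.11 and intercalated duct-like at -0.21. For the marker rule and thinning the cause was not tested.

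At least 1000 UMIs left 19379 control and 17632 null barcodes, and under 1% mitochondrial UMIs left 26344 and 22929. The count of ILC2-like nuclei was 0 in every planned clustering, 127 and 104 with markers alone, 5 and 6 when thinned, and 6 and 7 as a subcluster at resolutions 1.0 and 2.0 (none was found at 0.5). The share of immune nuclei could not be given, since macrophage-like was the sole immune name in each clustering. With at least 1000 UMIs, Tigd2 (-0.68), Kcna1 (-0.90) and Kcnip4 (1.91) turned in endothelial-like nuclei, and the cause was not tested. Ppargc1a in macrophage-like nuclei was at 0.43 after free RNA was subtracted. Acinar secretory products over all kept barcodes had a mean of -0.29, with Smr3a at -9.35, and gland growth genes in intercalated duct-like nuclei were at -0.27 with no minimum count. Of the values tried, 616 of 685 for genes and 333 of 341 for lists stayed within the counting interval or range of the planned value. For shares 93 of 146 stayed within it and 14 turned, and 30 of 42 counts stayed about the same. The range of a list came from the spread of its members' own ratios and often included 0. Rescaling and the few doublets could also move little, so the tallies are a weak check. Fewer named genes stayed named. With free RNA subtracted, 1 of 10 named genes was still named in luminal duct-like and in myoepithelial-like nuclei, 2 in fibroblast-like and 3 in intercalated duct-like and in ionocyte-like nuclei. With at least 1000 UMIs, 3 of 10 were still named in fibroblast-like nuclei. Depth limits the macrophage-like genes: at 20 UMIs over both libraries only large ratios have intervals that exclude 0.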

Other observations

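In ionocyte-like nuclei, Shisa9 had 56 control and 7 null UMIs (log2 ratio -2.63, -4.00 to -1.49) and the phosphodiesterase gene Pde7b 354 and 122 (-1.16, -1.47 to -0.86), while the cytoskeletal gene Tln1 had 16 and 40 (1.70, 0.83 to 2.63). In Schwann-like nuclei, the kinase gene Prkca had 119 and 275 UMIs (1.64, 1.33 to 1.96), and Gpc6, a heparan sulfate proteoglycan gene, had 130 and 25 (-1.95, -2.62 to -1.32). Gpc6 was also lower in intercalated duct-like nuclei (4976 and 3249 UMIs, -0.90) and in cluster 11 (342 and 104, -1.73). In cluster 11, Lrrk2 had 1761 and 734 UMIs (-1.28, -1.40 to -1.15) and Cntnap2 had 113 and 482 (2.08, 1.78 to 2.39).

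A subcluster of the macrophage-like cluster had 5 markers of NK cells or ILC1, among them Ncr1 and Eomes, and held 24 control and 20 null nuclei. Another, led by the cell division genes Kif23, Kif11 and Bub1b, held 3 and 8 nuclei. One led by Aldh1a2 and Clec9a held 10 and 9. Of the Y-linked genes, Ddx3y had 1 and 3 UMIs and Uty, Kdm5d and Eif2s3y had 0 in both libraries, and Xist was not among the features. Alas2, a gene of heme synthesis, had 227 control and 284 null UMIs over all kept barcodes (0.55, 0.29 to 0.81), unlike the globin genes.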
